A study of Mus musculus with 4 samples.

How the data were processed

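RNA levels were measured in the dentate gyrus of young male C57BL/6J mice at 4 times after contextual fear conditioning, with 1 Affymetrix murine array per time. Per the labels' descriptions, each animal received 3 foot shocks of 0.5 mA lasting 1 s, each preceded by 2 min in the conditioning box, and went back to its home cage 1 min after the last shock. RNA was taken 1, 2, 4 or 6 h later. The groups came from the sample titles. How many animals entered each array is not given in the sources used here, and untreated mice were not analysed here.

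The values deposited by the authors are intensities on a linear scale, 1 per probe set and array, for 12488 probe sets. The software that summarised the probes, its version and any background correction are not given in the sources used here. The deposited values themselves show how each array was scaled: the mean of the values between the percentiles 2 and 98 was 500 on every array to within 0.0167% between the highest and lowest array. Scaling each array to 1 common mean leaves a dim array with a raised background, so a scaled intensity is a level relative to the other probe sets of the same array.

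Probe sets were named from a platform annotation table, in which 10833 of them have 1 gene symbol, 396 have several and 1193 have none; 66 more are control probe sets. Of those with 1 symbol, 10817 were matched to a current symbol by Entrez identifier in a mouse RefSeq gene table (assembly GRCm38.p6), which was used for names and for the genomic span of genes. Probe sets with several symbols were left out of the gene results, and control probe sets were used only to describe the arrays. No genome build applies to the array values, so no coordinates are given.

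Each array was rescaled to a common mean between the percentiles 2 and 98. Values under the pooled percentile 40 of all scaled values, 136 intensity, were set to that floor, and log2 was taken. A gene was represented by its probe set with the highest mean log2 value before flooring, which gave 8251 genes. The plan fixed beforehand reads as the mean after flooring, so that choice was run as an alternative. A gene was counted as at least 2-fold higher or lower when both arrays lay above the floor and the ratio was at least 2, which is a log2 ratio of 1. Genes above the floor on 1 of the 2 arrays were counted apart, as bounds against the floor, and such a ratio is written as at least N-fold.

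With 1 array per time there is no spread between replicates, and no test across samples was made. The error that these arrays do hold was taken from genes with several probe sets above the floor: the SD of the difference between the log2 ratios of 2 probe sets of 1 gene, divided by the square root of 2. It covers neither animals nor preparations. The number of arrays limits the precision of every value.

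The 12 gene lists and 11 lists of cell type markers, the comparisons, the floor, the alternatives and the rule for named genes were fixed before the data were examined. The median log2 ratio of each list with at least 5 measured genes was placed among 10000 random lists of the same size. These were drawn from genes of the same mean level over all arrays of the setting, in 20 bins. A list outside the middle 95% of its random lists is called outside them; this describes these arrays and is no test. The standard error given with a list median is taken over its genes, which are not independent replicates.

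Genes are named by this rule: for each later time against 1 h, the 8 highest and 8 lowest log2 ratios among genes above the floor on both arrays; from each list, up to 4 members above the floor on all 4 arrays with the largest log2 ratio to 1 h in size at any later time; and, where measured, Fos, Egr1, Arc, Nr4a1, Junb, Dusp1, Homer1, Bdnf, Sgk1, Fkbp5, Per1 and Dbp. The list part of the rule picked 89 list entries, of which 85 had their largest ratio on the 2 h array. After that array was seen to stand apart, list members were therefore named by the same rule from the 1, 4 and 6 h arrays. The extremes of 4 h against 2 h and of 6 h against 4 h were named in the same way. Other probe sets of a named gene are given for some genes only, mostly where they went the other way. Arc has no probe set with its symbol alone, so it is not analysed here.

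The alternatives were the values as deposited, quantile normalization, cyclic loess normalization, scaling to the percentile 75, a floor at the percentile 20 or 60, a pseudocount equal to the floor value in place of the floor, the mean of all probe sets of a gene, and probe sets whose names end in a plain _at. For the time of the highest value each time was also left out in turn, with the floor kept at 136 intensity. Chosen after the data were seen were all other results without the 2 h array (with the floor at 114 intensity, and also with quantile or cyclic loess normalization of the other 3 arrays), list medians for 6 h against 4 h, the probe set of a gene chosen by its mean after flooring, and random lists matched on level in 5 bins and on genomic span in 8 bins.

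The counting step was tested on simulated data for 4 h against 1 h: of 5086 genes, 200 were given a log2 change of 2, of which 100% were recovered, while 78 unchanged genes also passed 2-fold. That change lies well past the threshold of 1 and the floor was not part of this simulation, so the recovery does not speak for ratios near the threshold. Comparisons that share the 1 h array were set beside 100 simulated sets of unchanged arrays, on the 5086 genes above the floor of 114 intensity at 1, 4 and 6 h. The noise of both simulations was drawn from the differences between 6 and 4 h, so it holds any real change between these and no noise peculiar to the 1 h array. Normalization used limma 3.58.1 in R 4.3.3; all other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.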

Results

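RNA levels in the dentate gyrus, the hippocampal region that holds the granule cells, were followed at 1, 2, 4 and 6 h after contextual fear conditioning, a training in which a mouse comes to link a place with foot shocks. Each time was represented by 1 array, so no value below has a replicate and no difference between times was tested across samples. Of 8251 genes, 5359 lay above the floor of 136 intensity at 1 h, 6102 at 2 h, 5407 at 4 h and 5335 at 6 h. All times follow training, so the comparisons ask how the transcript levels at later times differ from those at 1 h. Without untreated mice at each time, the hour of day was not told apart from time after training.

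The arrays at 1, 4 and 6 h ranked the probe sets alike, and the 2 h array did not. Across probe sets, which are not independent replicates, Spearman's rho was 0.928 for 4 h with 1 h, 0.929 for 6 h with 1 h and 0.946 for 6 h with 4 h, but 0.304 for 2 h with 1 h. The 9 probe sets of bacterial transcripts, which are added to a sample and are not RNA of the tissue, were higher at 2 h than the mean of the other arrays by a median of 18.3-fold (15.4 to 20.9-fold). Gapdh, a glycolytic enzyme gene, read 39712 intensity at its 3′ probe set at 1 h and 2502 at 2 h, and the cytoskeletal gene Actb read 36700 and 2128. Over 10 groups of probe sets of equal size, ordered by mean level at 1, 4 and 6 h, the median ran from 128 to 735 intensity at 2 h and from 12 to 2816 at 1 h.

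The 1 h array differed from the later ones in its control probe sets too. The 5′ probe set of Gapdh read 9164 intensity at 1 h, 25996 at 4 h and 27268 at 6 h, while the 3′ set read 39712, 32679 and 32974. The 5′ set of Gapdh, relative to its 3′ set, was higher than at 1 h by 1.79 at 4 h and 1.84 at 6 h on the log2 scale, and that of Actb by 0.50 and 0.65. The bacterial probe sets were lower than at 1 h, with median log2 ratios of -0.64 at 4 h and -0.67 at 6 h.

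**Figure D1:**
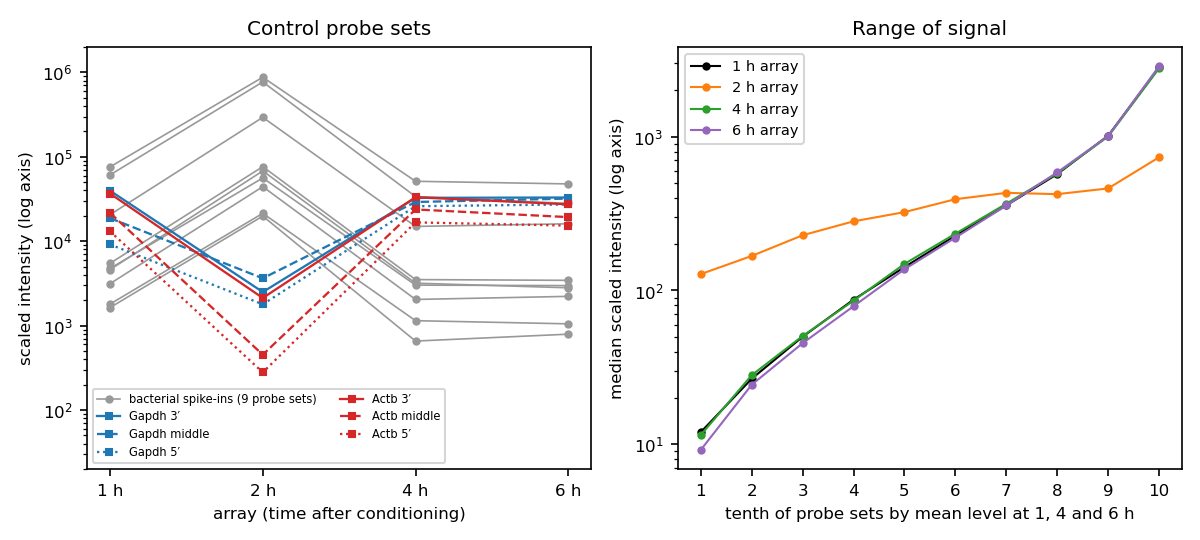
Left, scaled intensity (log axis) of the 9 bacterial spike-in probe sets and of the 3′, middle and 5′ probe sets of Gapdh and Actb on each array, 1 array per time; right, median scaled intensity (log axis) of 10 groups of probe sets ordered by mean level at 1, 4 and 6 h. The spike-ins peak at 2 h, where Gapdh and Actb read lowest and the range of signal narrows to 128 to 735.

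At 4 h, transcripts of glutamate receptor subunits and their postsynaptic scaffolds were, as a list, higher than at 1 h. Grik5, a kainate receptor subunit, read 1538 intensity at 4 h against 516 at 1 h, a log2 ratio of 1.58. Another probe set of Grik5 stood at 0.53. Dlg4, which encodes the scaffold protein PSD-95, had a log2 ratio of 1.49, its relative Dlg3 0.64 and the AMPA receptor subunit Gria3 0.85. These members were chosen for their size by the rule, while Gria2 stood at -0.05, Grik2 at 0.04 and Camk2b at 0.05. Of the 14 measured genes of this list 12 were higher at 4 h, 4 of them by at least 2-fold with bounds included, and the median log2 ratio was 0.51 (standard error 0.22), at percentile 100 of the random lists (0.37 without the 2 h array). Synaptic vesicle genes had a median of 0.27 (standard error 0.18, percentile 99.7), with 14 of 19 higher. Among them were Rab3a, a vesicle GTPase (log2 ratio 1.81), Cplx1, which binds the fusion complex (1.47), and the calcium sensors Syt1 (1.17) and Syt5 (0.86). On the same pair of arrays the 5′ signal of Gapdh relative to its 3′ signal was higher at 4 h by 1.79 on the log2 scale, and that of Actb by 0.50.

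The highest single ratio at 4 h was that of Kif1a, which lies outside these lists. Kif1a, a motor that carries vesicle precursors along axons, read 794 intensity at 4 h against 153 at 1 h (log2 ratio 2.38). Kif5a, another kinesin motor, had a log2 ratio of 2.01, Syt11, a synaptotagmin, 1.88, Rnd2, a small GTPase, 1.87, and Scn8a, a voltage-gated sodium channel, 1.86. Rnf112 (2.08), Rrp1 (2.06) and the metalloproteinase inhibitor Timp2 (1.88) complete the 8 highest. Across all genes, 109 were at least 2-fold higher and 58 at least 2-fold lower at 4 h among 5001 above the floor on both arrays; 56 and 32 more were so as bounds against the floor. With the 2 h array left out, the floor was 114 intensity and 5086 genes lay above it at 1, 4 and 6 h. Of these, 134 were at least 2-fold higher and 64 at least 2-fold lower at 4 h. Simulated unchanged arrays gave 34.48 and 33.84. Their noise came from 6 h against 4 h, with an SD per probe set of 0.33. That SD was 0.47 for 4 h against 1 h on these arrays. The simulation was thus quieter than this comparison, and the excess over it does not measure change.

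The choroid plexus and ependyma markers were lower at 4 h than at 1 h. Ttr, the thyroid hormone carrier that choroid plexus makes in large amounts, read 3007 intensity at 1 h and 252 at 4 h, a log2 ratio of -3.58 and the lowest of all genes above the floor on both arrays. Igf2, a growth factor of choroid plexus and meninges, had a log2 ratio of -1.26 and Kl, the klotho gene, -0.96. Folr1, a folate receptor, read 154 intensity at 1 h and lay below the floor at 4 h. Of the 7 measured markers 6 were lower, 4 of them by at least 2-fold with bounds included, and the median was -1.02 (standard error 0.58), at percentile 0 of the random lists. Over 12 alternatives the median ran from -1.23 to -0.32 and lay outside in all 12. Ptgds, the prostaglandin D synthase of meninges, choroid plexus and glia, read 19816 intensity at 1 h and 6334 at 4 h, a log2 ratio of -1.65. The other genes among the 8 lowest were Wdr5 (-2.14), Tradd (-2.07), Lamb1 (-1.61), Limk1 (-1.56), Snrp1c-ps2 (-1.53) and Pard3 (-1.52). Of the 8 lowest, 5 rest on probe sets of a type open to cross-hybridization, and another probe set of Limk1 had a log2 ratio of 0.19.

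Genes that neuronal activity induces with a delay were lower at 4 h than at 1 h. Their median log2 ratio was -0.33 (standard error 0.14, percentile 0.22, inside with the pseudocount), with 16 of 20 lower. Tiparp, a poly-ADP-ribose polymerase, had a log2 ratio of -1.14, the neuropeptide gene Cort -0.92, the glucocorticoid-activating enzyme Hsd11b1 -0.76 and the protease inhibitor Timp1 -0.59. Bdnf, the neurotrophin, read 3953 intensity at 1 h and 3622 at 4 h (log2 ratio -0.13). The 5′ to 3′ shift of Gapdh and Actb and the difference in spike-ins stand beside this group and the choroid plexus markers as well, since the same 1 h array enters.

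Immediate early genes, the fast transcriptional response to activity, lay inside their random lists between 1 and 4 h. Their median log2 ratio was -0.12 (percentile 15.3), with 13 of 27 higher and 14 lower; over probe sets with plain _at names, which leaves out that of Junb, it was -0.22 and outside the random lists (percentile 2.17). Fos read 254 intensity at 1 h and 208 at 4 h, Egr1 1034 and 781, and Dusp1 498 and 514. Nr4a1, an orphan nuclear receptor, read 430 at 1 h and lay below the floor at 4 h, at least 3.15-fold lower. Ier2 had a log2 ratio of -0.77 and Gadd45b -0.69, while Junb, from a probe set of a type open to cross-hybridization, was higher by 1.34. The probe set that represents Homer1 lay below the floor on all 4 arrays, and its other probe set did at 1, 4 and 6 h.

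Glucocorticoid-induced genes differed gene by gene between 1 and 4 h, with a median log2 ratio of -0.09 (percentile 24.9; -0.15 without the 2 h array). Sgk1, a kinase gene, read 1294 intensity at 1 h and 638 at 4 h (log2 ratio -1.02). Fkbp5, a chaperone of the glucocorticoid receptor, read 1119 and 1718 (0.62), Gpd1, a glycerol phosphate dehydrogenase, was higher by 1.01 and Hif3a by 0.85. The probe sets of Errfi1 opposed each other, with log2 ratios of 1.00 and -0.76. Circadian clock genes had a median of -0.03 (percentile 43.4): the repressor gene Cry2 was higher by 1.23 and the transcription factor gene Tef by 0.76, while Cry1 had a log2 ratio of -0.70 and Nr1d1 -0.69. Per1 read 380 intensity at 1 h and 306 at 4 h, and Dbp 469 and 456. Chaperone genes had a median of -0.11 (percentile 20.4), with Pdia6 at 1.75 (other probe sets at 1.40 and -0.11), Stip1 at 1.18, Hspe1 at -0.80 and Hspa1b at -0.35.

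Several other cell type lists stood outside the random lists at 4 h against 1 h. Oligodendrocyte markers had a median log2 ratio of 0.37 (percentile 98.5, 8 of 9 higher). Among them were the myelin genes Mag at 1.38 (another probe set at 0.22) and Mbp at 0.47 (another at -0.35). The actin-severing gene Gsn was at 0.94. Markers of newborn neurons and progenitors had a median of 0.40 (percentile 99.9, 10 of 14 higher, inside under 3 of 13 alternatives). Among them were the transcription factor gene Sox4 at 0.74, the microtubule regulator Stmn1 at 0.71 and Marcksl1 at 0.62. The 4 lower ones were the cyclin gene Ccnd2 at -0.81, Neurod1 at -0.28, Dcx at -0.12 and Mki67 at -0.09, so the list did not move as a whole. Markers of CA1 to CA3 pyramidal cells had a median of -0.30 (percentile 1.35, 7 of 12 lower; inside under 5), with Wfs1 at -0.98, Elavl4 at -0.65, Chgb at -0.60 and Nnat, in the other direction, at 1.24. Thalamus markers had a median of -0.38 (percentile 1.38, 5 of 8 lower, inside under 4). Tcf7l2 was at -0.68, Adarb1 at -0.66 (another probe set at -0.11), Tnnt1 at -0.65 and Zic1 at -0.29. Over plain _at probe sets the thalamus median was -0.01 (percentile 49.7). Ribosomal protein genes were lower by little and together, with a median of -0.22 (percentile 1.31, inside under 7) and 22 of 25 lower, among them Rpl13a at -0.62, Rps10 at -0.45 and Rpl22 at -0.07. The 1 h array's lower 5′ signal accompanied each of these groups.

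The remaining lists lay inside the middle 95% of their random lists at 4 h against 1 h. Their median log2 ratios were -0.15 for oxidative phosphorylation genes (percentile 3.23, but outside under 3 of 13 alternatives, at 1.96 without the 2 h array), -0.04 for proteasome genes, 0.04 for chromatin regulators, -0.11 for NF-kappaB and inflammatory genes (-0.05 without the 2 h array), 0.10 for dentate granule cells, -0.12 for interneurons, -0.07 for astrocytes, 0.13 for microglia (-0.08 without the 2 h array) and -0.17 for endothelial and mural cells. Of 22 lists 9 lay outside. Lists of genes that vary independently would put 1.1 there, but genes of a list can vary together, and some genes are in several lists. The number outside is therefore no measure of an excess over chance. For genes with several probe sets the SD of a log2 ratio per probe set was 0.46. The log2 ratios of all 5001 genes above the floor on both arrays had an SD of 0.45. Of 15 such genes past 2-fold another probe set went the same way in 7, and was past 2-fold too in 2. Where the 2 h array was not required, these numbers were 10 and 3 of 28. For most of these genes another probe set thus did not bear out the direction.

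**Figure D2:**
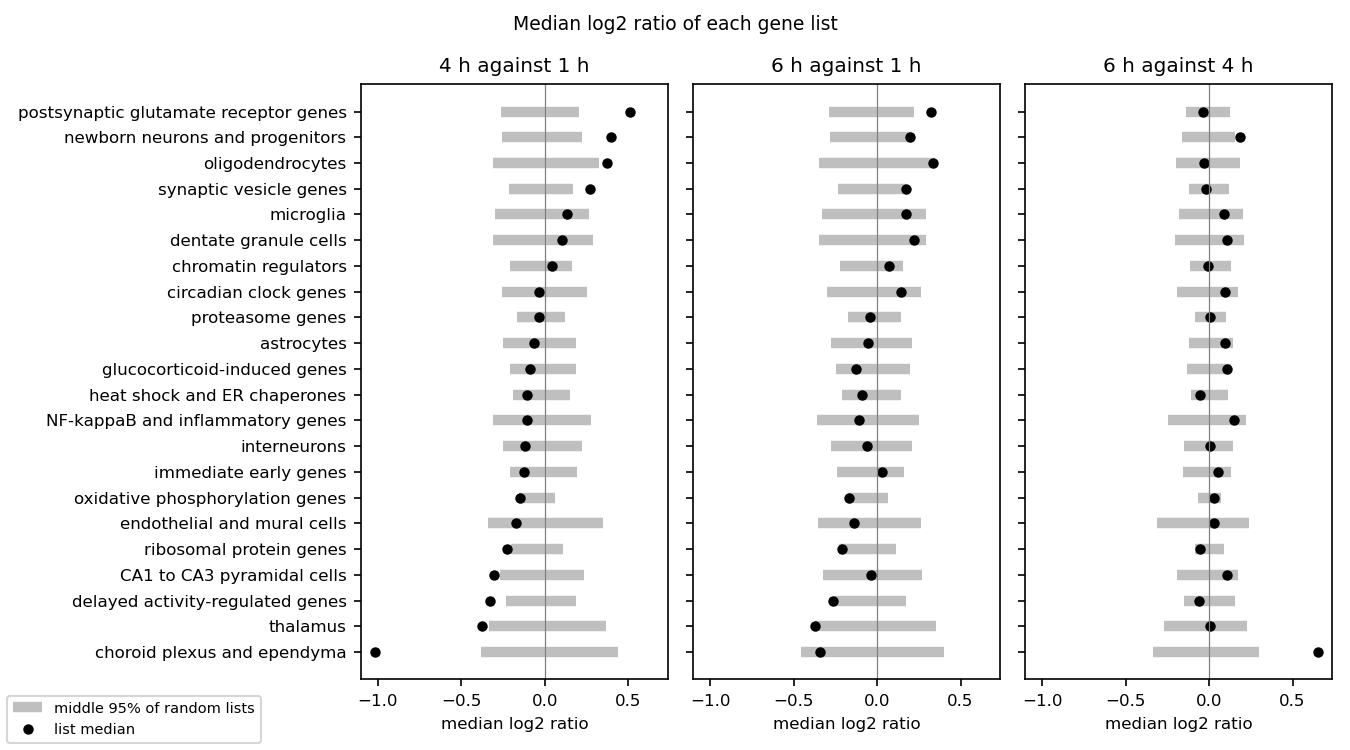
Median log2 ratio of each gene list (points) for 4 h against 1 h, 6 h against 1 h and 6 h against 4 h, 1 array per time, with the middle 95% of 10000 random lists of matched level (bars). Glutamate receptor genes lie at 0.51 and choroid plexus markers at -1.02 at 4 h against 1 h, and choroid plexus markers at 0.65 at 6 h against 4 h.

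At 6 h the glutamate receptor genes also read higher than at 1 h. Both comparisons use the same 1 h array, so for no list is 6 h an independent repeat of 4 h. The vesicle genes were outside their random lists in the main settings but inside under 8 of 13 alternatives. Grik5 read 1797 intensity against 516 at 1 h (log2 ratio 1.80, another probe set at 0.90). Dlg4 was higher by 1.37, Dlg3 by 1.18 and Gria3 by 0.54. The list of postsynaptic glutamate receptor genes had a median of 0.33 (standard error 0.23, percentile 99.6), with 12 of 14 higher. It lay inside under 2 of 13 alternatives, with a median of 0.15 under cyclic loess normalization and 0.06 with the floor at the percentile 60. Synaptic vesicle genes had a median of 0.17 (standard error 0.20, percentile 97.6, 12 of 19 higher), with Cplx1 at 1.79, Rab3a at 1.79, Syt5 at 0.94 and Syt1 at 0.78. The highest single genes were Syt11 at 2.18, Chmp6, a membrane remodelling gene, at 2.06, Usp22, a deubiquitinase gene, at 2.06, Kif1a at 2.05, Gabarap, which acts in receptor trafficking and autophagy, at 1.97, B4galt2 at 1.96, Rnd2 at 1.95 and Sult4a1 at 1.93. The 5′ signal of Gapdh relative to its 3′ signal was higher at 6 h than at 1 h by 1.84 on the log2 scale.

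The lowest genes at 6 h against 1 h were Ctrb1 (log2 ratio -2.07), the kinase gene Hipk2 (-1.75), Ttr (-1.44), Mapt, which encodes the microtubule protein tau (-1.43), Vax1 (-1.38), Daxx (-1.36), Lmnb2 (-1.35) and Akap8 (-1.32, with another probe set at 0.81). Other probe sets of Mapt stood at -0.81 and -0.33. Delayed activity-regulated genes had a median of -0.26 (standard error 0.16, percentile 1.82, 14 of 20 lower), a call lost under 8 of 13 alternatives (percentile 7.05 without the 2 h array). Of the members of that list, Hsd11b1 was at -1.22, Cort at -0.98, Tiparp at -0.59 and Timp1, in the other direction, at 0.93. Bdnf had a log2 ratio of -0.34. Immediate early genes had a median of 0.03 (percentile 71.2), or -0.03 (percentile 54.7) without the 2 h array: Fos read 162 intensity at 6 h (log2 ratio -0.65), Egr1 843 (-0.29), Nr4a1 248 (-0.79) and Junb 440 (0.85). Sgk1 had a log2 ratio of -0.89 and Fkbp5 of 0.27 in a glucocorticoid list with a median of -0.13 (percentile 19.8; -0.19 without the 2 h array). Among clock genes (median 0.14, percentile 87.7) Cry2 was higher by 1.35, Tef by 0.76, Dbp by 0.48 and Per1 by 0.39, while Cry1 had a log2 ratio of -0.99 and Nr1d1 of -0.97.

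Choroid plexus markers at 6 h lay inside the random lists against 1 h, with a median log2 ratio of -0.34 (percentile 7.76; -0.58 and outside over plain _at probe sets and with the mean of probe sets), Igf2 at -0.33 and Kl at -0.34. Thalamus markers had a median of -0.37 (percentile 2.47), just outside the random lists but inside under 12 of 13 alternatives, with Tcf7l2 at -0.76 and Zic1 at 0.95. The other medians, inside the middle 95%, were -0.21 for ribosomal protein genes (outside under 2 of 13 alternatives), -0.17 for oxidative phosphorylation genes (outside under 3, at percentile 1.44 without the 2 h array), -0.09 for chaperones, -0.04 for proteasome genes, 0.07 for chromatin regulators, -0.11 for NF-kappaB and inflammatory genes (-0.27 at percentile 7.15 without the 2 h array), 0.22 for dentate granule cells, -0.04 for CA1 to CA3 cells (-0.13 without it), -0.06 for interneurons, 0.20 for newborn neurons (outside under 1), -0.05 for astrocytes, 0.33 for oligodendrocytes (outside under 3, without the 2 h array at the same median), 0.17 for microglia (percentile 99.82 and so outside with the pseudocount) and -0.14 for endothelial and mural cells (-0.22 without it).

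Across genes, 136 were at least 2-fold higher and 53 at least 2-fold lower at 6 h than at 1 h among 4963 above the floor on both arrays, with 63 and 32 more as bounds. The SD of a log2 ratio was 0.47 per probe set and 0.47 across these genes. Of 15 genes past 2-fold with several probe sets, another went the same way in 7 and was past 2-fold too in 2. Where the 2 h array was not required, these numbers were 18 and 4 of 35. Without the 2 h array, with the floor at 114 intensity, 162 were higher and 68 lower at 6 h among 5086 genes above the floor at 1, 4 and 6 h, where simulated unchanged arrays gave 34.64 and 34.08. In that set 95 were at least 2-fold higher at both later times and 15 lower at both, which is 70.9% of the 134 higher at 4 h and 23.4% of the 64 lower. Simulated unchanged arrays sharing the 1 h array gave 8.71 and 8.29 genes at both times, 25.3% and 24.5% of their shorter lists. As a share, only the higher genes exceeded the simulation. The covariance of the log2 ratios across genes was 0.168 against 0.0583 simulated, and the correlation 0.742 against 0.500. The simulated noise came from 6 h against 4 h, with an SD per probe set of 0.33. That SD was 0.49 for 6 h against 1 h where the 2 h array was not required. Noise of the single 1 h array enters both ratios, cannot be split off and was not simulated. Part or all of the excess in counts, share, covariance and correlation may therefore come from it. Of 22 lists 4 lay outside the middle 95%, where lists of genes that vary independently would put 1.1, which is again no measure of an excess over chance.

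**Figure D3:**
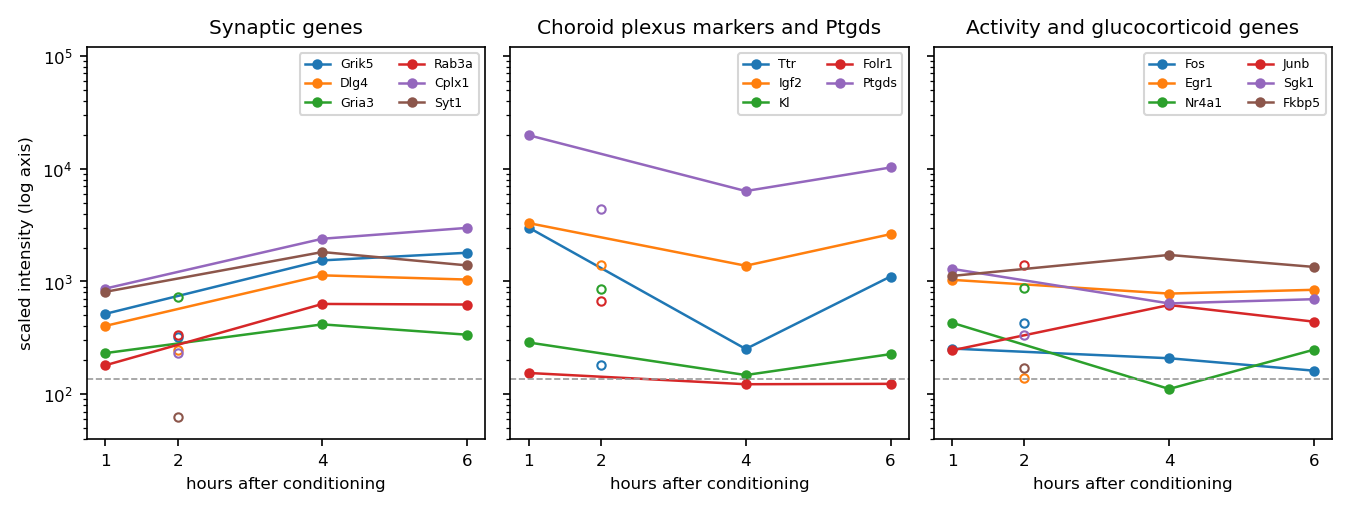
Scaled intensity (log axis) of named synaptic genes, choroid plexus markers with Ptgds, and activity and glucocorticoid genes by time after conditioning, 1 array per time; filled points joined by lines are 1, 4 and 6 h, open points the 2 h array, and the dashed line the floor of 136. Grik5 and Rab3a lie higher at 4 and 6 h than at 1 h, and Ttr goes from 3007 to 252 to 1106.

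Between 4 and 6 h few genes differed, and choroid plexus markers were higher at 6 h. The 4 h array also enters 4 h against 1 h, so this rise is no independent reversal of the fall there. Ttr read 252 intensity at 4 h and 1106 at 6 h (log2 ratio 2.13), Igf2 1379 and 2626 (0.93) and Kl 148 and 227 (0.61); the 6 measured choroid plexus and ependyma markers were all higher, bounds against the floor included, with a median of 0.65 (standard error 0.35, percentile 99.98). Markers of newborn neurons had a median of 0.18 (percentile 98.9, inside under 5 of 13 alternatives), with Ccnd2 at 0.98 and Marcksl1 at 0.56. Glutamate receptor genes had a median of -0.04 and synaptic vesicle genes of -0.02, both inside the random lists. The 8 highest genes also held Wdr5 (2.16), Chmp6 (1.97), Tradd (1.76), Limk1 (1.75), Snrp1c-ps2 (1.73), the potassium channel gene Kcnj9 (1.60) and Timp1 (1.52). Ttr, Wdr5, Tradd, Limk1 and Snrp1c-ps2 were also among the 8 lowest at 4 h against 1 h. Another probe set stood at 0.18 for Limk1 and at 0.11 for Kcnj9. The lowest were Ctrb1 (-2.54), Adh7 (-2.22), Tbc1d10a (-2.02), the receptor gene Notch2 (-1.56), Gm10046 (-1.37), Shbg (-1.36), Ppfibp2 (-1.36) and 2210016L21Rik (-1.34).

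At 6 h against 4 h, 31 genes were at least 2-fold higher and 22 lower among 5052, or 1.05%. Medians inside the random lists were 0.05 for immediate early genes, -0.06 for delayed activity-regulated genes, 0.11 for glucocorticoid-induced genes (0.05 without the 2 h array) and 0.10 for clock genes. The SD of a log2 ratio per probe set was 0.33, and 4 of the 8 highest and 4 of the 8 lowest genes rested on probe sets of a type open to cross-hybridization. With a floor at the percentile 60, 8 genes passed 2-fold in place of 53; the choroid plexus list moved inside its random lists with the pseudocount (median 0.08), and the lists for CA1 to CA3 cells and thalamus moved outside under 1 alternative each.

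At 2 h abundant transcripts read far lower than at 1 h and dim ones higher. Actg1, a cytoskeletal actin gene, read 18006 intensity at 1 h and 251 at 2 h (log2 ratio -6.17); the phosphatase subunit gene Ppp2r1a (-5.92), the G protein gene Gnas (-5.88), Itm2c (-5.83), the ribosomal gene Rps3 (-5.76), Tspyl4 (-5.67), the apolipoprotein gene Clu (-5.37) and Dbi (-5.26) followed. The highest were Rbfox2 (5.10), Stt3a (4.64), Usp25 (4.29), Aanat (4.21), Rps13 (4.15), Zfp787 (3.85), Rgs5 (3.77) and Cryzl2 (3.71), of which 6 rest on probe sets of a type open to cross-hybridization. The ribosomal genes Rps3 and Rps13 stood at opposite ends. Oxidative phosphorylation genes had a median log2 ratio of -2.32 (standard error 0.36, percentile 0.03). The random lists were matched on the mean level over all 4 arrays, which includes the 2 h array itself. A gene that read low at 2 h was so set beside genes less abundant at the other times. This percentile therefore does not separate the list from the fall of abundant transcripts on that array. The other 22 lists lay inside their random lists in the main settings. Of these, proteasome genes were outside and low under 4 of 10 alternatives, chaperones under 3, synaptic vesicle genes under 3, delayed activity-regulated genes under 3 and ribosomal protein genes under 1. Blood cell markers, measured in 5 genes at this time alone, had a median of 0.37. The bacterial spike-ins were higher at 2 h than at 1 h by a median log2 ratio of 3.66.

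In numbers, 1274 genes were at least 2-fold higher and 1280 lower at 2 h than at 1 h among 4230, with 1279 and 809 more as bounds. The comparison of 4 h with 2 h shares the 2 h array, so it is no independent reversal. In it 1246 genes were at least 2-fold higher and 1277 lower among 4285. The highest were Actg1 (6.23), Itm2c (5.79), Ppp2r1a (5.70), Rps3 (5.57), Tspyl4 (5.41), the tubulin gene Tuba1c (5.38), Gnas (5.37) and Clu (5.32), and the lowest were Stt3a (-4.72), Rps13 (-4.59), Rbfox2 (-4.37), Snx17 (-3.80, with another probe set at 1.63), Cryzl2 (-3.71), Dock5 (-3.70), St6galnac2 (-3.69) and Col6a2 (-3.62). The SD of a log2 ratio per probe set was 1.53 for each of these comparisons. Among 298 genes past 2-fold at 2 h against 1 h, another probe set went the same way in 59.4%.

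Among 3832 genes above the floor at all 4 times, 2650 had a range of at least 2-fold. The highest value fell at 2 h in 43.6% and the lowest at 2 h in 53.9% of them, where equal shares would be 25%. Actg1, Gnas and Clu had their lowest value at 2 h, and Rbfox2 and Cryzl2 their highest. With the 2 h array left out and the floor kept at 136 intensity, 282 of 4823 genes had such a range, and the lowest value fell at 1 h in 58.2%, at 4 h in 22.7% and at 6 h in 19.1%, with Grik5, Rab3a and Kif1a among those lowest at 1 h. The highest value fell at 1 h in 29.8%, at 4 h in 28.4% and at 6 h in 41.8%.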

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

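Tests chosen only after the data were seen are the list medians for 6 h against 4 h, those with the probe set of a gene chosen after flooring, and those without the 2 h array (other than for the time of the highest value); those matched on genomic span, also chosen then, stand under the other observations. No result called outside its random lists changed sign under any alternative run, and no count changed which direction held more genes except for 2 h against 1 h and 4 h against 2 h. Of the counts and shares under alternatives 175 stayed within their limits and 51 moved; of the list medians 993 stayed within the standard error over their genes and 84 moved. The values as deposited moved 0 of 113 results beyond these limits. Those values already had equal trimmed means to within 0.0167%, so this alternative nearly repeats the main settings and could move little. It is counted in the tallies of alternatives all the same. With the floor at the percentile 60 the choroid plexus list and the endothelial and mural list had under 5 genes and gave no value for 4 and 6 h, nor did the choroid plexus list at 6 h against 4 h over plain _at probe sets. Blood cell markers at 2 h gave none under quantile or cyclic loess normalization, the floor at the percentile 60 and plain _at probe sets. Choosing the probe set of a gene after flooring gave another one for 174 of 8251 genes, and counts of 2539, 169, 189, 2514 and 53 in place of 2554, 167, 189, 2523 and 53; the ribosomal list at 4 h moved inside (percentile 3.83) and the delayed activity list at 2 h outside (percentile 1.17). No paired analysis was possible because each time has 1 array and no test was made. Signal over background limits how many genes are tested, since the floor sets which enter, and the number of arrays limits every value.

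Counts of genes at least 2-fold apart moved with the floor, since it sets how many genes enter. With the floor at the percentile 20 they were 4327 (2 h against 1 h, in place of 2554), 513 (4 h against 1 h, 167), 526 (6 h against 1 h, 189), 4303 (4 h against 2 h, 2523) and 280 (6 h against 4 h, 53). With the percentile 60 they were 1110, 58, 77, 1064 and 8 in the same order. With the pseudocount they were 4311 for 2 h against 1 h and 4200 for 4 h against 2 h; at 4 h against 1 h it called 157, of which 69 were called in the main settings too, at 6 h against 1 h 167 and 82, and at 6 h against 4 h 54 and 13. Without the 2 h array the counts were 201 (161 shared), 238 (185 shared) and 76 (53 shared) for 4 h against 1 h, 6 h against 1 h and 6 h against 4 h.

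The share of higher genes moved by over 10 points under cyclic loess, to 64.9% (1621 higher, 875 lower) for 2 h against 1 h from 49.9%, and to 34.6% (857 and 1619) for 4 h against 2 h from 49.4%. The floor at the percentile 60 gave 82.8% for 4 h against 1 h (from 65.3%), 84.4% for 6 h against 1 h (from 72.0%) and 6 higher with 2 lower for 6 h against 4 h (from 58.5%), and the percentile 20 gave 59.3% for 6 h against 1 h. The median log2 ratio of all genes moved to 0.52 (cyclic loess) and -0.22 (percentile 75) at 2 h against 1 h, and to -0.54, 0.22 and -0.13 (cyclic loess, percentile 75, quantile) at 4 h against 2 h; the pseudocount gave 0.28 and -0.27; ratios with the 2 h array are relative to these shifts. Lists outside the random lists at 4 and 6 h against 1 h numbered 13, and 8 under quantile and 8 under cyclic loess normalization; the cause was not tested.

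The share of genes highest at 2 h, 43.6%, became 48.3% (quantile), 60.2% (cyclic loess), 36.9% (percentile 75), 37.5% (floor at the percentile 60), 55.9% (pseudocount), 41.4% (mean of probe sets), 41.1% (plain _at), 46.9% without 1 h and 45.8% without 6 h. The share highest at 1 h without the 2 h array, 29.8%, became 18.0% (floor at the percentile 60) and 24.3% (pseudocount). The SD per probe set was larger with the floor at the percentile 20 (0.59 for 4 h against 1 h, 0.59 for 6 h against 1 h, 0.44 for 6 h against 4 h, 1.77 for 2 h against 1 h, 1.75 for 4 h against 2 h) and smaller at the percentile 60 (0.39, 0.39, 0.25, 1.34 and 1.33); quantile normalization gave 0.44 for 6 h against 1 h, 0.31 for 6 h against 4 h, 1.79 for 2 h against 1 h and 1.77 for 4 h against 2 h. The cause was not tested in these cases.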

Other observations

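Tests chosen only after the result was seen are those on the spike-ins, on the correlation of the 2 h array, on the 5′ and 3′ probe sets and on the choroid plexus markers without Ttr; the tests on genomic span were added after the data were seen but before their own result was.

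Members with the largest ratios in other lists, chosen for their size by the rule, went in both directions. In the proteasome, Psmd3, a regulatory particle subunit, read 505 intensity at 1 h, 1431 at 4 h and 1335 at 6 h (log2 ratio to 1 h of 1.40 at 6 h), and the activator subunit Psme1 was higher by 0.81 at 4 h and 1.23 at 6 h, while the core subunit Psma7 had log2 ratios of -0.79 and -0.97 and Psme3 of -0.75 and -0.73. In oxidative phosphorylation, the complex I gene Ndufa9 was higher by 1.16 and 1.12, while the complex III gene Uqcrc2 had log2 ratios of -0.52 and -0.87, and the ATP synthase genes Atp5d of -0.85 and -0.54 and Atp5pb of 0.25 and -0.88. Other probe sets of Atp5d stood at -0.10 and -0.08, at -0.03 and -0.18 and, as bounds against the floor, at 0.87 and 0.34. Among chromatin regulators, the histone deacetylase gene Hdac3 read 522 intensity at 1 h, 182 at 4 h and 438 at 6 h, the DNA methyltransferase gene Dnmt1 was higher at 4 h by 0.92 and at 6 h by 0.53, and Mbd2, a methyl-DNA binding protein gene, had a log2 ratio of -0.87 at 4 h; Rbbp4 had log2 ratios of -0.38 and -0.63. In the NF-kappaB list, the inhibitor gene Nfkbia had log2 ratios of -0.80 and -0.57 and Sod2 of -0.16 and -0.50. Stat3 was higher by 0.20 and 0.56, and Relb, with the floor at 114 intensity, by 0.40 and 0.68. Among interneuron markers Calb2 was higher by 0.36 and 0.54 and Dlx1 had log2 ratios of -0.36 and -0.59, as Tac1 had of -0.43 and -0.03 with the floor at 114 intensity. The ribosomal gene Rpl22 was higher by 0.50 at 6 h.

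Glial and vascular markers were mixed. The astrocyte glutamate transporter gene Slc1a2 was higher by 0.62 at 4 h and 0.93 at 6 h and the water channel gene Aqp4 by 0.40 and 0.65, while Sparcl1 had log2 ratios of -0.32 and -0.56 and Glul of -0.19 and -0.56 (another probe set at 0.25 and 0.04). The oligodendrocyte gene Mog was higher by 0.22 and 0.43. The microglial complement genes C1qc (0.45 and 0.30) and C1qb (0.17 and 0.60) and the receptor gene Cx3cr1 (0.26 and 0.41) were higher, while Cd68 had log2 ratios of -0.39 and 0.42. Of the vascular markers, the glucose transporter gene Slc2a1 had log2 ratios of -0.68 and -0.22, Itm2a of -0.42 and -0.47 and Cldn5 of 0.15 and -0.57, while Acta2, with the floor at 114 intensity, was higher by 0.91 and 0.28. The haemoglobin genes Hba-a1 (-0.39 and -0.68) and Hbb-b2 (-0.18 and -0.65) were lower. Of the granule cell markers, Dsp was higher by 0.83 and 0.36 and Npy1r by 0.63 and 0.84, while Lct had log2 ratios of -0.31 and -0.21 and Il16 of -0.32 and -0.04.

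The 2 h array stands apart from the other 3. A change in the tissue alone is argued against, since the lowest of the 9 spike-in probe sets, which are not RNA of the tissue, was still higher at 2 h than the mean of the others by 3.94 on the log2 scale. Rows in a shuffled order are also argued against, since the lowest Spearman's rho of the 2 h array with another array was 0.302 across probe sets. Little labelled RNA of the sample on that array may account for the pattern: the spike-ins were higher by a median of 4.19, as scaling a dim array to a common mean would give. A change at 2 h under this pattern stays open and was not tested apart from it.

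Synaptic lists read lower at 1 h than at 4 and 6 h, though the vesicle list at 6 h lay inside its random lists under 8 of 13 alternatives. A longer genomic span is argued against as the whole cause. Against random lists matched on level and span the glutamate receptor list at 4 h against 1 h lay at percentile 99.8 and the vesicle list at 99.5. At 6 h against 1 h the vesicle list lay inside these random lists, at percentile 96.6, so this covers 4 h for that list. Across 5079 genes span was nearly unrelated to the ratio at 4 h against 1 h (Spearman's rho -0.03), so matching on it could move these percentiles little. Genomic span is not transcript length, which was not used here. These values therefore cannot decide on transcript length or on a loss of 5′ signal. Less intact RNA at 1 h may contribute: the 5′ probe sets of Gapdh and Actb were lower relative to their 3′ sets at 1 h in all 4 comparisons, by at least 0.50 on the log2 scale. That shift is in 2 control genes and does not show how far the synaptic probe sets followed it. The time after conditioning stays open too and was not tested, because each time has 1 array.

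Ttr differs between the 1, 4 and 6 h arrays. Different amounts of choroid plexus, a tissue next to the hippocampus, in the dissections may account for it: with the floor at 114 intensity, as used without the 2 h array, the 7 measured choroid plexus and ependyma markers other than Ttr had a median log2 ratio of -0.96 at 4 h against 1 h, bounds included, with 6 of 7 lower, and 6 of 6 were higher at 6 h than at 4 h, with a median of 0.66. Both comparisons share the 4 h array, so the rise is no independent reversal of the fall. The marker list was fixed beforehand, and its most abundant genes here were Igf2, at 3292 intensity at 1 h, and Ttr, at 3007. With Ttr the list had a median of -1.11 at 4 h against 1 h in these settings, with 7 of 8 lower. Leaving Ttr out could therefore change the median little, and it adds no support beyond the list result itself. Only 4 members, Ttr among them, lay above that floor at 1, 4 and 6 h. The time after conditioning stays open as another explanation and was not tested, because each time has 1 array.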
